A study of Mus musculus with 26 samples.

How the data were processed

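The study measured transcripts in pancreatic islets of male and female C57Bl/6 mice. Per the labels and the series description, the mice received corn oil or TCDD at 20 ng per kg per day, in injections given 2 times per week, and ate chow or a diet with 45% of its energy from fat, and islets were taken at week 12. Per the labels' protocols, islet RNA was stored in RNAlater, extracted with the RNeasy Micro kit, made into libraries with the TempO-Seq mouse whole transcriptome panel, pooled and sequenced on an Illumina NextSeq 500. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14. The aligner, the counting step and the probe manifest are not given in the sources used here, so the position of each probe in its gene is not known.

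The table the authors deposited holds raw counts of sequencing reads per detector probe, with 30146 probes of 21450 gene symbols, of which 6290 have several probes. All 26 columns were matched to a label through the well and index name that the label carries. The counts carry no molecular identifiers. Replicate libraries, which come from different mice, differed by more than counting error. Over 33 pairs of replicates the lowest chi-square per degree of freedom was 13.2, and their log levels correlated at 0.95 to 0.98. How much of this excess comes from the mice and how much from repeated reads was not tested. Reads without molecular identifiers are not independent molecules, so floors of 3 counts cover counting error only. Library totals ran from 9019116 to 40043259 with a median of 13439152.

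Libraries were grouped by sex, chemical and diet as labelled. The single TCDD-treated male on chow had a mean of its own in the model and entered none of the 11 comparisons, only the correlations over 12 male libraries. Animal numbers differ between all libraries, so nothing paired them. Probes were kept when at least 3 libraries exceeded the CPM of 10 counts in a library of median size, which is 0.744 CPM, and 22547 probes of 16130 symbols remained. One negative binomial model with a mean per group was fitted to all 26 libraries with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the robust quasi-likelihood fit and the quasi-likelihood F test. The common biological coefficient of variation was 0.378 and the median prior degrees of freedom 15.2. Probes passed at a Benjamini-Hochberg adjusted p under 0.05, within each of 11 comparisons. These were TCDD against oil in females on chow, females on HFD and males on HFD and the mean of these 3, HFD against chow in oil-treated females, oil-treated males and TCDD-treated females, males against females on oil and chow, and 3 interactions. The SE of a log2 fold change was its size divided by the square root of F. Principal components were computed on log2 of CPM plus 0.5.

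Gene lists, 21 of pathways and 12 of cell types, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it and with fry, and adjusted over the 33 lists of a comparison. Members of lists were also counted after adjustment over the list alone. Gene positions are those of GENCODE M21 on GRCm38, matched by symbol, which found 16015 of the 16130 symbols (99.3%). Named genes followed a rule: for each comparison up to 12 higher and 12 lower passing probes with the smallest p, or the 5 probes with the smallest p where fewer than 5 passed, a panel of 18 receptor, hormone and beta cell genes, up to 4 passing members of a list or else its 2 members with the smallest p, and the Y-linked genes and Cyp1a1 as a check of labels. Some results that this rule selects are not reported here. Xist was not analysed here. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

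The test was checked on simulated data, negative binomial counts drawn with the real library sizes, probe means and dispersions and with known changes in 1 group. Of 100 probes changed 2-fold, 19 to 35 were called in 7 comparisons of groups of this size, of 100 changed 4-fold, 52 to 65, and 0 to 7 unchanged probes were called. A list shifted 2-fold was recovered in each comparison with 0 of the 32 other lists called. The probes were drawn independently of each other, with no shared structure among libraries. The check therefore does not bear on false calls of probes or lists that correlation between genes can cause.

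The alternatives were RLE and upper-quartile scaling, no filter, a filter of 50 counts, the fit without robust estimation, DESeq2 1.42.0, probes summed per symbol, the plate part as a factor, only the groups compared, and each library left out in turn. Those added after seeing the data were the acinar score as a covariate, acinar probes left out, 3 libraries that stood apart left out, 3 female libraries with Y-linked counts left out, and 1 library left out of both arms at once for HFD against chow in TCDD-treated females. A planned fit without libraries of low depth was not run, since 0 libraries met its limit.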

Results

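Islets of the pancreas, the clusters of hormone-secreting cells that include the insulin-making beta cells, were profiled from 26 mice of 8 groups, 1 library per mouse. The assay was TempO-Seq, in which pairs of short probes that bind side by side on a transcript are ligated, amplified and counted. The female groups held 3 mice on corn oil and chow, 4 on TCDD and chow, 3 on corn oil and high-fat diet (HFD) and 4 on TCDD and HFD. The male groups held 4 mice on corn oil and chow, 1 on TCDD and chow, 3 on corn oil and HFD and 4 on TCDD and HFD. TCDD is a dioxin that binds the aryl hydrocarbon receptor, a transcription factor that switches on enzymes for foreign chemicals. Library totals ran from 9019116 to 40043259 counts, with a median of 13439152, and 19845 to 27794 of the 30146 probes had at least 1 count. Levels below are CPM, normalised counts scaled to a common library size, as mean ± SD over the mice of a group, and log2 fold changes are given ± SE. Adjusted p values of single probes are from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction over 22547 probes.

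The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, which only males carry, summed to between 140 and 215 CPM in the 12 male libraries and between 0 and 5.63 CPM in the 14 female libraries. A library at 0 allows up to 3 counts, which is 0.0749 to 0.333 CPM across the 26 libraries. The insulin genes Ins1 and Ins2 took 6.52 ± 0.562% of counts in oil-treated females on chow (n = 3) and 10.7 ± 1.29% in oil-treated males on chow (n = 4). The glucagon gene Gcg took 4.59 ± 1.07% and 1.64 ± 0.48% in the same groups. Over the 7 groups with at least 3 mice, the mean of Sst, the somatostatin of delta cells, ran from 4900 ± 1530 to 12900 ± 5180 CPM and that of Ppy, pancreatic polypeptide, from 5610 ± 2150 to 10300 ± 2290 CPM. The beta cell genes Nkx6-1, a transcription factor, and Ucn3, a peptide of mature cells, ran from 88.3 ± 9.84 to 167 ± 32.8 CPM and from 17.3 ± 2.52 to 40.7 ± 5.53 CPM, and the Pdx1 probe read at most 0.329 ± 0.335 CPM. Genes of acinar cells, the enzyme-making cells that surround islets, took 2.88 to 19.6% per library. Genes of stellate cells and fibroblasts, which make collagen, summed to 213, 502 and 75.6 CPM in the 3 libraries of oil-treated females on chow and to between 50.9 and 161 CPM in the other 23. The first principal component carried 19.9% of the variance, and replicates 1 and 2 of oil-treated females on chow and replicate 2 of TCDD-treated females on chow lay apart from the rest on it, at -0.51, -0.335 and -0.47 against -0.169 to 0.269. The second component carried 14%.

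The question of the TCDD comparisons is which islet transcripts differ after exposure. Cyp1a1 encodes a cytochrome P450 that the aryl hydrocarbon receptor induces, and its probe Cyp1a1_29719 read 26.3 ± 11.6 CPM in TCDD-treated females on chow (n = 4) and 16 ± 16.2 CPM in oil-treated ones (n = 3). The log2 fold change of 0.71 ± 0.68 did not pass (edgeR adjusted p = 1). Over the alternatives it ran from -0.12 to 1.98, turning to -0.12 without the 3 libraries that lay apart, which leaves replicate 3 of the oil group at 34.7 CPM. In females on HFD Cyp1a1 read 20.3 ± 4.18 CPM with TCDD (n = 4) and 31.3 ± 8.94 CPM with oil (n = 3), a log2 fold change of -0.62 ± 0.66 (edgeR adjusted p = 0.95). In males on HFD it read 21.5 ± 11.5 CPM (n = 4) and 16.5 ± 12.1 CPM (n = 3), a log2 fold change of 0.37 ± 0.68 (edgeR adjusted p = 1). Tiparp, a target of the same receptor that limits its activity, read 68.7 ± 19 against 50.2 ± 8.51 CPM in females on chow, 129 ± 25.6 against 101 ± 10.9 CPM in females on HFD and 63.8 ± 15.5 against 61.2 ± 26.1 CPM in males on HFD. None of these differences passed. Nqo1, a quinone reductase, read 26.2 ± 7.44 against 19 ± 6.09 CPM, 26.7 ± 3 against 33.8 ± 5.18 CPM and 24.9 ± 12 against 20.4 ± 9.98 CPM in the same order, and none of these passed. Probe Cyp1a1_79654 had group means of 16.6 to 41.8 CPM, and its fold changes did not pass either. Summed over its probes, Cyp1a1 read 32 to 46.3 CPM in TCDD-treated females on HFD and 51.6 to 85.9 CPM in oil-treated ones. Each TCDD library there lay below each oil library, the reverse of induction. In females on chow and males on HFD the ranges of the sum overlapped. As a check of labels Cyp1a1 thus did not show the exposure in any of these groups. The probes of Cyp1a2, Ahrr and Cyp1b1 and 1 further probe of Cyp1a1 had group means below 1 CPM. The Cyp1a1 gene lies on chromosome 9 from 57687928 to 57703824 on the plus strand of GRCm38.

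**Figure D1:**
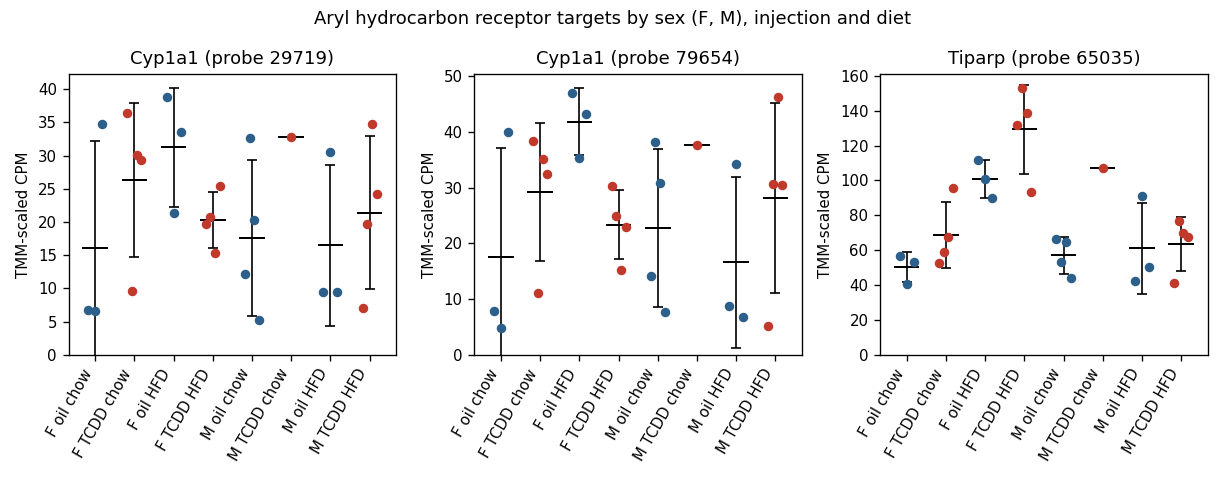
Normalised counts (CPM) of probes Cyp1a1_29719, Cyp1a1_79654 and Tiparp_65035 in each library by group, with points for single mice and bars for mean ± SD. In females on chow, females on HFD and males on HFD the ranges of TCDD (red) and corn oil (blue) overlap for Cyp1a1_29719, and Tiparp is highest in TCDD-treated females on HFD, at 129 ± 25.6 CPM. The sum over the Cyp1a1 probes, which is not drawn, was lower in each TCDD-treated than in each oil-treated female on HFD.

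TCDD against oil in females on chow separated no gene past the threshold. The smallest p belonged to Tagln, an actin-binding protein of smooth muscle and fibroblasts, at 1.04 ± 0.668 CPM with TCDD (n = 4) and 13.1 ± 17.5 CPM with oil (n = 3), a log2 fold change of -3.66 ± 0.66 (edgeR adjusted p = 0.09). Krt23, an epithelial keratin, read 0.912 ± 0.707 against 8.78 ± 9.21 CPM (-3.24 ± 0.72). Gsta4, a glutathione transferase, read 0.993 ± 0.39 against 45.5 ± 74.9 CPM (-5.50 ± 1.05). Dynll1, a dynein light chain, read 16.2 ± 1.56 against 28.9 ± 5.95 CPM (-0.83 ± 0.19). Mal, a membrane protein of epithelia, read 0.079 ± 0.115 against 15.3 ± 25.1 CPM. Its fold change turned sign without the 3 libraries that lay apart, which leaves 1 oil-treated female. Of 22547 probes 0 passed in edgeR, 795 had an unadjusted p under 0.05 and DESeq2 called 13. Without replicate 1, 2 or 3 of oil-treated females on chow edgeR called 4, 0 and 21. Tagln (adjusted p = 0.02 and 0.00052) and Gsta4 (0.026 and 0.0075) passed without replicate 1 and without replicate 3. Krt23 and Dynll1 (0.045 each) passed without replicate 3. That fit kept as controls only replicates 1 and 2, which lay apart, with 213 and 502 CPM of stellate and fibroblast genes against 75.6 CPM in replicate 3.

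Among 33 lists of genes, camera with a preset correlation of 0.01 called 10 in TCDD-treated females on chow, and none passed with an estimated correlation, where the smallest adjusted p was 0.22. All 28 probes of the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum, were higher, with a median log2 fold change of 0.30 (camera adjusted p = 4.1e-05, adjusted p = 0.65 with an estimated correlation). Of the 21 probes of the stellate and fibroblast list 19 were lower, with a median of -1.89 (camera adjusted p = 3e-11, adjusted p = 0.22 with an estimated correlation). Col1a1, a fibrillar collagen of that list, read 1.4 ± 0.784 against 12.7 ± 14.5 CPM (n = 4 and 3). Replicates 1 and 2 of oil-treated females on chow carried this fall, and without them, which leaves 1 oil-treated female, the list's median was 0.23. The other 8 calls were integrated stress response, beta cell identity, secretion machinery and cholesterol synthesis higher, and aryl hydrocarbon receptor targets, disallowed genes, apoptosis and p53 targets and duct cell lower. Disallowed genes are ones that beta cells keep silent. Most of these calls rested on the same 2 libraries. Without both, the median went from -1.08 to -0.08 for receptor targets (-0.02 without replicate 2 alone), -0.68 to 0.37 for disallowed genes, -0.22 to 0.13 for duct cell and -0.19 to -0.05 for apoptosis and p53 targets. It went from 0.14 to -0.11 for beta cell identity, 0.15 to -0.07 for secretion machinery, 0.27 to 0.05 for integrated stress response, 0.30 to 0.10 for cholesterol synthesis and 0.30 to 0.26 for unfolded protein response. Within the receptor targets 0 probes passed over all probes and 3 passed as lower when adjusted over the list alone.

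TCDD against oil in females on HFD showed its smallest p for Kdr, the main receptor of endothelial cells for the growth factor VEGF, at 4.2 ± 1.28 CPM with TCDD (n = 4) and 11.5 ± 3.06 CPM with oil (n = 3), a log2 fold change of -1.44 ± 0.27 (edgeR adjusted p = 0.15). Zfp39, a zinc finger protein, read 22.3 ± 3.71 against 43.3 ± 2.89 CPM (-0.95 ± 0.20). Lrrc10b, a leucine-rich repeat protein, read 15.5 ± 2.51 against 29.3 ± 2.61 CPM (-0.92 ± 0.20). Higher values came from Tsc22d3, a mediator of glucocorticoid action, at 70.8 ± 16.9 against 36 ± 4.26 CPM (0.97 ± 0.20), and Ilf2, an RNA-binding protein, at 91.6 ± 10 against 45.2 ± 6.83 CPM (1.02 ± 0.22). Each of these 5 genes had an edgeR adjusted p of 0.15. Slc2a2, the main glucose transporter of mouse beta cells, read 5.17 ± 1.57 against 20.3 ± 3.32 CPM (edgeR adjusted p = 0.62). Of 22547 probes 0 passed in edgeR, 1439 had an unadjusted p under 0.05 and DESeq2 called 41, and with any 1 library left out edgeR still called 0. A fit of only the groups compared called 153, and edgeR called 1 with the acinar score as a covariate and 2 without the 3 libraries that lay apart.

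Camera called 9 of the 33 lists in this comparison, and the smallest adjusted p with an estimated correlation was 0.16. Beta cell identity genes had a median log2 fold change of -0.31, with 26 of 31 probes lower, 1 passing as higher and 4 as lower when adjusted over the list alone (camera adjusted p = 9.9e-06, adjusted p = 0.47 with an estimated correlation). Interferon response genes had a median of -0.38, with 31 of 38 probes lower (camera adjusted p = 2.1e-05, adjusted p = 0.16 with an estimated correlation). Apoptosis and p53 targets had a median of 0.29, with 24 of 30 probes higher (camera adjusted p = 0.0011, adjusted p = 0.16 with an estimated correlation). Cholesterol synthesis was also called higher, and oxidative phosphorylation, secretion machinery, inflammatory and NF-kB genes, immediate early genes and the estrogen-responsive list were called lower, the last with a median of -0.41 but a mean of 0.12.

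TCDD against oil in males on HFD gave its 5 smallest p values for genes with group means of at most 5.23 CPM. Tspan6, a tetraspanin of the cell membrane, read 2.02 ± 0.52 CPM with TCDD (n = 4) and 5.23 ± 2.04 CPM with oil (n = 3), a log2 fold change of -1.36 ± 0.38 (edgeR adjusted p = 1). Gcnt1, a glycosyltransferase, read 0.427 ± 0.0974 against 1.91 ± 1.1 CPM (-2.15 ± 0.60). Cyb561a3, an iron reductase, read 0.073 ± 0.0885 against 1.21 ± 0.291 CPM, and Mylk, a myosin kinase, 0.0224 ± 0.0448 against 0.848 ± 0.297 CPM. Gm5239, a predicted gene, was at 0 in all 4 TCDD libraries and at 0.845 ± 0.608 CPM with oil. Of 22547 probes 0 passed in edgeR, 435 had an unadjusted p under 0.05 and DESeq2 called 3. Camera called 4 lists, namely cholesterol synthesis (median 0.17) and alpha cell (0.27) higher and acinar cell (-0.14) and macrophage and dendritic cell (-0.26) lower, and the smallest adjusted p with an estimated correlation was 0.87.

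The mean TCDD effect over the 3 strata also passed for no gene. Levels in this paragraph pool the mice of the 3 strata, while each fold change is the mean of the 3 changes within strata. The ratio of the levels can therefore differ from the fold change. Reg3a, a secreted antimicrobial lectin, read 4.81 ± 6.01 CPM with TCDD (n = 12) and 59.9 ± 73.8 CPM with oil (n = 9), a log2 fold change of -3.45 ± 0.81 (edgeR adjusted p = 0.95). Hist1h1d, a linker histone, read 12.2 ± 8.86 against 24.2 ± 8.84 CPM (-1.11 ± 0.25). Tspan6 read 2.58 ± 0.869 against 4.72 ± 1.86 CPM (-0.87 ± 0.22). Fam76b, a nuclear speckle protein, read 12.9 ± 5.16 against 8.12 ± 1.86 CPM (0.62 ± 0.15). Arhgef38, an exchange factor, read 0.393 ± 0.415 against 1 ± 0.521 CPM (-2.74 ± 0.63). Of 22547 probes 0 passed in edgeR, 1125 had an unadjusted p under 0.05 and DESeq2 called 2. Cholesterol synthesis had 31 of 33 probes higher with a median log2 fold change of 0.19, and 2 passed when adjusted over the list alone (camera adjusted p = 2.1e-08, adjusted p = 0.24 with an estimated correlation). Camera also called unfolded protein response (0.13), integrated stress response (0.20) and circadian clock (0.20) higher, and the estrogen-responsive list (-0.33), macrophage and dendritic cell (-0.11) and stellate and fibroblast (-0.57) lower. None of these 7 lists passed with an estimated correlation, where the smallest adjusted p was 0.24. Without replicates 1 and 2 of oil-treated females on chow 2 of the 7 medians turned sign, macrophage and dendritic cell (0.03) and stellate and fibroblast (0.13). Across probes, which are not independent replicates, the fold changes of the 3 strata had correlations of -0.07 between females on chow and on HFD, 0.05 between females on chow and males on HFD, and -0.04 between females and males on HFD.

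HFD against chow in TCDD-treated females passed for Akr1b3, Kdr, Slc2a2, G6pc2 and Mafa among other genes (n = 4 and 4 throughout). Akr1b3, an aldose reductase that turns glucose into sorbitol, rose from 25.7 ± 7.96 to 274 ± 79 CPM, a log2 fold change of 3.42 ± 0.48 (edgeR adjusted p = 0.0017). Kdr fell from 15.5 ± 3.1 to 4.2 ± 1.28 CPM (-1.87 ± 0.26, adjusted p = 7.1e-05). Slc2a2 fell from 45.3 ± 21.9 to 5.17 ± 1.57 CPM (-3.13 ± 0.67, adjusted p = 0.017). G6pc2, the glucose-6-phosphatase of islets, fell from 123 ± 41 to 27.4 ± 8.22 CPM (-2.16 ± 0.45, adjusted p = 0.016). Mafa, a transcription factor of mature beta cells, fell from 52.9 ± 12 to 23.7 ± 2.89 CPM (-1.16 ± 0.28, adjusted p = 0.024). In all, 887 of 22547 probes passed in edgeR, standing for 787 genes, with 471 higher and 416 lower. The count depended on single libraries: it was 228, 182, 132 and 1769 without replicates 1, 2, 3 and 4 of the chow group and 571, 209 and 142 without replicates 2, 3 and 4 of the HFD group. It was 200 without the 3 libraries that lay apart on the first component, 277 with the acinar score as a covariate and 1 without the 3 TCDD-treated female libraries with 2.77 to 5.63 CPM of Y-linked genes. Akr1b3 and Kdr passed in all 8 fits with 1 library left out. Slc2a2 and G6pc2 missed the threshold without replicate 3 of the chow group (adjusted p = 0.06 and 0.054) and without replicate 4 of the HFD group (0.071 and 0.064). Mafa passed only without replicate 4 of the chow group or replicate 2 of the HFD group, and its highest adjusted p was 0.082.

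The smallest p among genes that rose belonged to Mtmr2, a phosphoinositide phosphatase, from 37.3 ± 9.88 to 103 ± 21.3 CPM on probe Mtmr2_64311 (log2 fold change 1.47 ± 0.17, edgeR adjusted p = 1.7e-05), and its other 3 probes gave 1.16 ± 0.15, 1.17 ± 0.15 and 1.28 ± 0.20. Ilf2 rose from 411 ± 96.9 to 1380 ± 240 CPM (1.74 ± 0.21, adjusted p = 6.4e-05) and on a further probe by 1.47 ± 0.20. Gm648, a predicted gene, rose from 4.73 ± 0.376 to 22.6 ± 5.14 CPM (2.26 ± 0.30), and Tns3, a focal adhesion protein, from 33.5 ± 7.35 to 84.4 ± 18 CPM (1.33 ± 0.19). Stk39, a kinase of ion transport, rose from 98.6 ± 19.6 to 206 ± 39.7 CPM (1.07 ± 0.17). Ptprb, an endothelial phosphatase, rose from 3.18 ± 0.939 to 12.3 ± 2.51 CPM (1.95 ± 0.32). Tsc22d3 rose from 32.5 ± 7.15 to 70.8 ± 16.9 CPM (1.12 ± 0.19, adjusted p = 0.0017). Igfbp3, which binds insulin-like growth factors, fell from 214 ± 62 to 60.7 ± 15.9 CPM (-1.82 ± 0.29, adjusted p = 0.0036). Ifit1, an interferon-induced protein, fell from 26.1 ± 8.62 to 9.01 ± 3.19 CPM (-1.52 ± 0.27, adjusted p = 0.0045). Vil1, an actin bundler of microvilli, fell from 100 ± 22.3 to 34.3 ± 8.72 CPM (-1.55 ± 0.27). Clip4, a microtubule-linked protein, fell from 6.77 ± 1.45 to 1.02 ± 0.659 CPM (-2.60 ± 0.47) and Lrrc10b from 34.3 ± 2.76 to 15.5 ± 2.51 CPM (-1.15 ± 0.18). Further falls were those of Anxa11, an annexin (-1.11 ± 0.20), Cep89, a centrosome protein (-1.40 ± 0.26), Npcd (-1.24 ± 0.24), Pcbd1, a cofactor of HNF1 factors (-1.11 ± 0.21), and Ap3m2, an adaptor of vesicle sorting (-1.08 ± 0.21). Each probe of this paragraph passed in all 8 fits with 1 library left out.

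**Figure D2:**
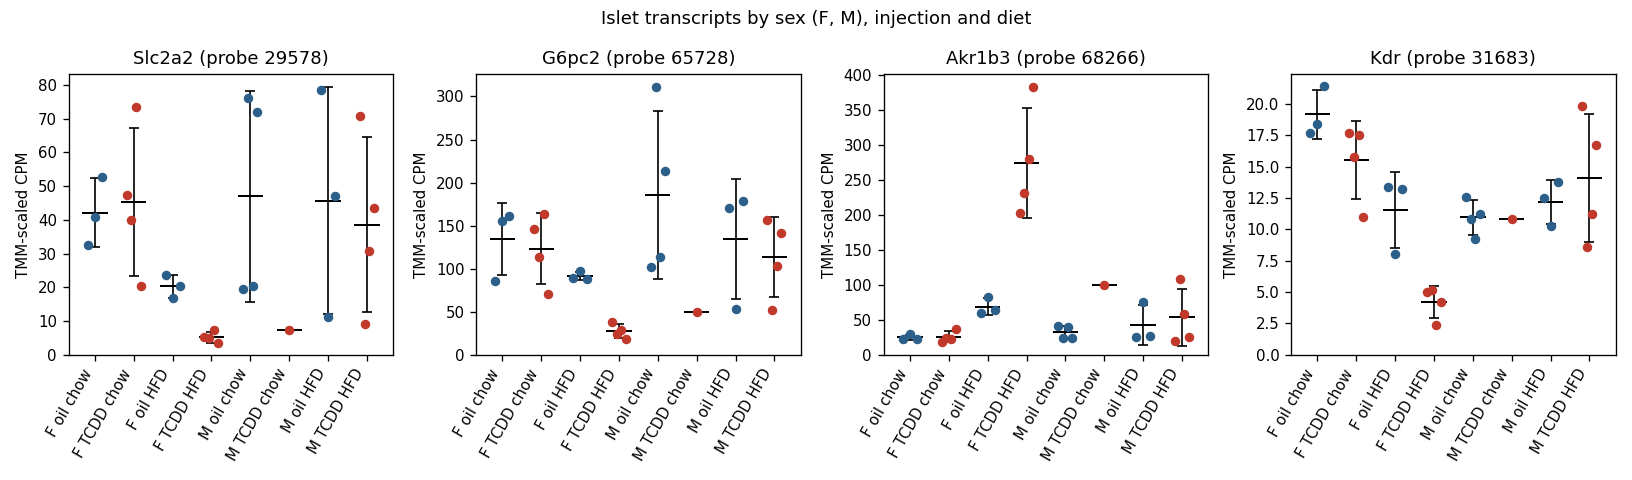
Normalised counts (CPM) of probes Slc2a2_29578, G6pc2_65728, Akr1b3_68266 and Kdr_31683 in each library by group, with points for single mice and bars for mean ± SD. In TCDD-treated females on HFD Akr1b3 reads 274 ± 79 CPM and Slc2a2 5.17 ± 1.57 CPM, against 25.7 ± 7.96 and 45.3 ± 21.9 CPM on chow.

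For HFD in TCDD-treated females camera called 12 of the 33 lists, and none passed with an estimated correlation, where the smallest adjusted p was 0.36. Of 28 unfolded protein response probes all were higher, with a median log2 fold change of 0.74, and 3 passed over all probes and 18 adjusted over the list alone (camera adjusted p = 3.5e-14, adjusted p = 0.36 with an estimated correlation). Sel1l, which clears misfolded proteins, rose from 477 ± 149 to 940 ± 213 CPM. Dnajb11, a chaperone, rose from 96.2 ± 21.2 to 177 ± 31 CPM, and Pdia6, a disulfide isomerase, from 6.93 ± 2.99 to 15.7 ± 3.03 CPM. In the integrated stress response 4 probes passed as higher over all probes and 6 adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.36 with an estimated correlation). Atf4, its central transcription factor, rose from 402 ± 110 to 636 ± 31.3 CPM. Ppp1r15a, which ends the response, rose from 34 ± 7.38 to 84 ± 11.7 CPM, and Psat1, of serine synthesis, from 4.29 ± 1.97 to 13.5 ± 3.22 CPM. In beta cell identity 1 probe passed as higher and 5 as lower over all probes, and 3 and 9 adjusted over the list alone (camera adjusted p = 0.0086, adjusted p = 0.62 with an estimated correlation). Pcsk1, a proinsulin convertase, rose from 25.1 ± 8.8 to 55.7 ± 6.77 CPM, and Pax6, an endocrine transcription factor, fell from 351 ± 61.9 to 240 ± 3.56 CPM. Interferon response genes had a median of -0.65 (camera adjusted p = 0.0002, adjusted p = 0.36 with an estimated correlation). Macrophage and dendritic cell genes had a median of -0.68 with 4 probes passing as lower over all probes and 6 adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.40 with an estimated correlation), and the 4 were probes of H2-Ab1 and H2-Aa, which present antigen. Acinar genes had a median of 0.68 with no probe passing (camera adjusted p = 0.00011, adjusted p = 0.72 with an estimated correlation).

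Of the 54 probes named for HFD in TCDD-treated females 30, 28, 30 and 52 passed without replicates 1, 2, 3 and 4 of the chow group. Without replicates 1, 2, 3 and 4 of the HFD group 47, 40, 30 and 25 passed. All 54 kept their direction in these fits. Camera called 6 further lists in TCDD-treated females, again with none passing at an estimated correlation: apoptosis and p53 targets (median 0.29), prolactin and serotonin genes (0.56) and cholesterol synthesis (0.31) higher, and the estrogen-responsive list (-0.92), delta cell (-0.82) and lymphocyte (-1.33) lower. Members of lists that camera did not call passed singly. Tiparp rose from 68.7 ± 19 to 129 ± 25.6 CPM among receptor targets, and Gpx2, a glutathione peroxidase of the oxidative stress response, from 15.4 ± 5.1 to 42.1 ± 3.22 CPM. The clock genes Nr1d2, Clock and Nr1d1 rose from 31.8 ± 5.23 to 53.7 ± 7.89, from 123 ± 30.2 to 202 ± 50.1 and from 25.1 ± 4.93 to 43.9 ± 9.33 CPM. In secretion machinery Scg3, a granule protein, fell from 249 ± 23 to 145 ± 15.8 CPM and Snap25, which fuses granules with the membrane, rose from 5.32 ± 1.53 to 12.4 ± 2.09 CPM. Acly of fatty acid synthesis fell from 824 ± 91.1 to 570 ± 47.8 CPM, Ehhadh of fatty acid oxidation from 17.2 ± 3.06 to 9.8 ± 2.5 CPM and Cycs of oxidative phosphorylation from 37 ± 1.98 to 22.9 ± 2.58 CPM. Eno1 of glycolysis rose from 129 ± 9.89 to 180 ± 13.2 CPM, and Nfkb1 of the inflammatory list from 20 ± 4.28 to 34 ± 6.38 CPM. Spp1, a secreted protein on the duct list, rose from 57.2 ± 16.4 to 325 ± 112 CPM. Among endothelial genes Esm1 and Flt1 fell from 229 ± 64.6 to 132 ± 24.5 and from 56.1 ± 9.43 to 35.3 ± 2.13 CPM, and Cd34 rose from 58.1 ± 17.5 to 92.7 ± 12 CPM. No probe passed over all probes, and camera made no call, for disallowed genes, cell cycle, immediate early genes, hypoxia, alpha cell, PP cell, stellate and fibroblast, Schwann cell, adipocyte or erythroid cell.

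HFD against chow in oil-treated females passed for 3 clock genes and 3 collagens among its 22 probes (n = 3 and 3 throughout), and camera did not call the circadian clock list (adjusted p = 0.16). Cry1, a repressor of the circadian clock, rose from 28.5 ± 5.49 to 66.4 ± 17.4 CPM, a log2 fold change of 1.22 ± 0.23 (edgeR adjusted p = 0.045). Nfil3, a clock-controlled repressor, rose from 47.1 ± 14.4 to 142 ± 9.49 CPM (1.60 ± 0.31, adjusted p = 0.046). Per3, a further clock gene, fell from 24.1 ± 5.68 to 8 ± 2.83 CPM (-1.59 ± 0.30, adjusted p = 0.045). Col5a2, Col6a1 and Col18a1, which encode collagens, fell from 9.02 ± 7.1 to 1.12 ± 0.585, from 7.14 ± 4.6 to 1.27 ± 0.0937 and from 7.01 ± 6.88 to 0.827 ± 0.278 CPM. Vim, an intermediate filament of mesenchymal cells, fell from 87.8 ± 32.7 to 29.9 ± 1.84 CPM. In all, 22 probes of 21 genes passed in edgeR, 10 higher and 12 lower. The count was 0 without replicate 1 or 2 of the chow group or of the HFD group, 1 without replicate 3 of the HFD group and 458 without replicate 3 of the chow group, and 0 without the 3 libraries that lay apart. All 22 kept their direction in these fits with 1 library left out.

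Fam184a, a coiled-coil protein, rose in oil-treated females on 2 probes, by 1.16 ± 0.22 and 1.07 ± 0.22 log2. Pla2g2f, a secreted phospholipase, rose from 10.8 ± 2.09 to 31.7 ± 2.98 CPM, and Serpina7, a thyroxine carrier, from 6.32 ± 1.44 to 19.8 ± 4.35 CPM. Ell2, an elongation factor of secretory cells, rose from 185 ± 19.8 to 316 ± 29.1 CPM. Sgpp1, a sphingolipid phosphatase, rose from 74 ± 11.2 to 125 ± 11.3 CPM, and Fam174b from 31.9 ± 3.92 to 60.1 ± 10.9 CPM. Bex2, a regulator of cell survival, rose from 48.4 ± 5.82 to 86.5 ± 11.9 CPM. Krt23 fell from 8.78 ± 9.21 to 0.412 ± 0.329 CPM and Tagln from 13.1 ± 17.5 to 1.23 ± 0.256 CPM. Tpm2, a tropomyosin, fell from 13.4 ± 13.6 to 2.36 ± 0.084 CPM. Tgfb2, a growth factor, fell from 7.4 ± 3.31 to 1.77 ± 0.495 CPM, and Capg, an actin cap, from 12.5 ± 6.52 to 3.19 ± 0.159 CPM. Clip4 fell from 9.88 ± 2.97 to 1.78 ± 0.186 CPM and Fam107b from 37.4 ± 28.5 to 11.5 ± 2.49 CPM. All 28 unfolded protein response probes were higher with a median of 0.95, of which 0 passed over all probes and 26 adjusted over the list alone (camera adjusted p = 7e-22, adjusted p = 0.18 with an estimated correlation). Xbp1, a transcription factor of that response, read 393 ± 33.2 against 234 ± 25.5 CPM. Stellate and fibroblast genes had a median of -3.49, with 1 probe passing as lower over all probes and 18 adjusted over the list alone (camera adjusted p = 1.2e-09, adjusted p = 0.18 with an estimated correlation), and the median was -1.04 without replicates 1 and 2 of the chow group. In the integrated stress response 0 probes passed over all probes and 7 as higher adjusted over the list alone (camera adjusted p = 8.9e-07, adjusted p = 0.18 with an estimated correlation). Ins1 read 30100 ± 6570 against 14300 ± 2790 CPM and Ins2 73500 ± 19700 against 43300 ± 7720 CPM, with edgeR adjusted p of 0.072 and 0.07. Camera called 13 lists in this comparison and none passed with an estimated correlation. The others were secretion machinery (median 0.16), prolactin and serotonin genes (0.75), glycolysis (0.26), immediate early genes (0.44), beta cell identity (0.12, with a mean of -0.02) and cholesterol synthesis (0.22, with a mean of -0.07) higher. Disallowed genes (-0.62), macrophage and dendritic cell (-0.79), lymphocyte (-1.31) and Schwann cell (-2.32) were lower. Without replicates 1 and 2 of the chow group, which leaves 1 library there, 3 of the 13 medians turned sign (beta cell identity -0.18, secretion machinery -0.06, disallowed genes 0.01) and 7 more shrank by over 1.5 times, while unfolded protein response (0.88), integrated stress response (0.40) and glycolysis (0.27) did not.

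HFD against chow in oil-treated males passed for no gene. Gad1, which makes the transmitter GABA, read 2.61 ± 1.09 CPM on HFD (n = 3) and 19.9 ± 17.8 CPM on chow (n = 4), a log2 fold change of -2.90 ± 0.73 (edgeR adjusted p = 1), and -3.30 ± 0.89 on its other probe. Myo16, a myosin, read 5.84 ± 3.53 against 0.86 ± 0.711 CPM (2.70 ± 0.68). Klk13, a kallikrein protease, read 1.02 ± 0.359 against 0.0318 ± 0.0368 CPM, and Myo18b, a muscle myosin, read 1.06 ± 0.92 CPM on HFD and 0 in all 4 chow libraries. Of 22547 probes 0 passed in edgeR, 764 had an unadjusted p under 0.05 and DESeq2 called 0. Acinar genes had 33 of 34 probes higher with a median of 1.26 (camera adjusted p = 1.3e-13, adjusted p = 0.74 with an estimated correlation). Camera also called unfolded protein response (0.41) higher and beta cell identity (-0.14) and cholesterol synthesis (-0.20) lower, and none of the 4 lists passed with an estimated correlation, where the smallest adjusted p was 0.74.

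Of the 887 probes that passed for diet in TCDD-treated females, 808 (91.1%) had the same sign of diet effect in oil-treated females and 539 (60.8%) in oil-treated males, where all tested probes gave 68.1% and 52.2%. In the direction of the first, their median log2 fold change was 0.86 in TCDD-treated females, 0.44 in oil-treated females and 0.06 in oil-treated males. The 3 diet comparisons share no libraries. Of single probes only Clip4 passed in both female comparisons, where chance gives 0.865 probes. The count of 22 in oil-treated females on which this rests was 556 in DESeq2 and 1209 in a fit of only the groups compared. Across all probes, which are not independent replicates, the fold changes of the 2 female comparisons had a Pearson correlation of 0.29 and a Spearman correlation of 0.42, and oil-treated females against oil-treated males 0.00 and 0.01. Slc2a2 read 20.3 ± 3.32 CPM on HFD in oil-treated females and 45.6 ± 33.7 CPM in oil-treated males.

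**Figure D3:**
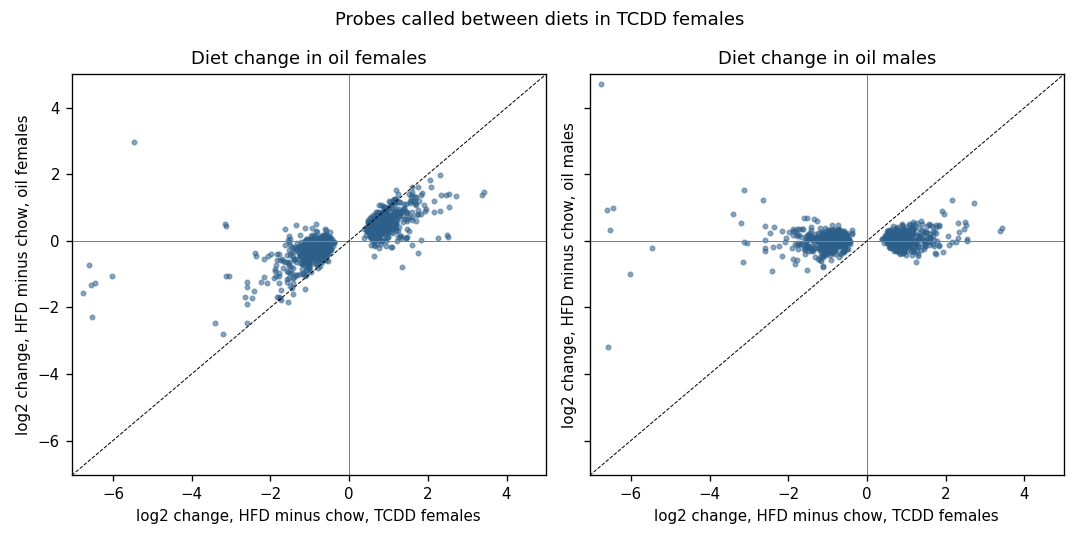
Log2 difference between HFD and chow of the 887 probes that passed in TCDD-treated females, on the horizontal axis for TCDD-treated females and on the vertical axis for oil-treated females and for oil-treated males, 1 point per probe and a dashed line of equal change. In oil-treated females 808 probes lie on the same side of 0 as in TCDD-treated females, and in oil-treated males 539.

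Between males and females on oil and chow sex-linked genes, hormones and cell type markers were among the genes that passed (n = 4 and 3 throughout). Kdm5d, a Y-linked histone demethylase, read 10.9 ± 2.51 CPM in males and 0 in all 3 females (edgeR adjusted p = 3.1e-07). Uty, a further Y-linked demethylase, read 82.6 ± 19.6 against 0.0858 ± 0.0922 CPM. Ins2 was higher in males at 75400 ± 11700 against 43300 ± 7720 CPM, a log2 fold change of 0.80 ± 0.16 (edgeR adjusted p = 0.0081). Iapp, the amyloid peptide released with insulin, was higher at 19600 ± 2780 against 11100 ± 3170 CPM (0.82 ± 0.18, adjusted p = 0.015). Gcg was lower in males at 15700 ± 4510 against 40400 ± 8990 CPM (-1.36 ± 0.33, adjusted p = 0.046). In all, 274 probes of 263 genes passed in edgeR, 107 higher and 167 lower in males. Of these 270 had a symbol in the annotation, with 32 on the Y chromosome, all higher, 4 higher and 22 lower on the X, and 69 higher and 143 lower on autosomes. In a fit of the 21571 probes of autosomal genes alone 135 passed. The count was 95, 73 and 704 without replicates 1, 2 and 3 of the females, 161, 91 and 106 without replicates 1, 2 and 3 of the males, and 11 without the 3 libraries that lay apart, which leaves 1 female. Ins2 and Iapp missed the threshold without female replicate 1 or 2 or male replicate 2 (highest adjusted p = 0.077 and 0.15), and Gcg passed only without male replicate 4 (highest adjusted p = 0.23).

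Among the 12 probes with the smallest p that were higher in males, 9 named predicted genes annotated on the Y chromosome, which occur in near-identical copies, so their probes may count several copies at once. Gm20873 read 32.4 ± 10 against 0.0611 ± 0.106 CPM and Gm21882 15.9 ± 4.85 against 1.23 ± 0.909 CPM. Ins1 was higher in males at 26800 ± 3620 against 14300 ± 2790 CPM (0.91 ± 0.22, edgeR adjusted p = 0.041), and it is a near copy of Ins2, so the probes may share transcripts. Scg2, a granule protein, read 8040 ± 700 against 4970 ± 1290 CPM (0.69 ± 0.16). Irx1 and Irx2, transcription factors of alpha cells, were lower in males at 22 ± 3.75 against 61.7 ± 15.4 CPM (-1.49 ± 0.27) and 9.53 ± 3.41 against 25 ± 7.48 CPM (-1.38 ± 0.26). Ptprz1, a delta cell phosphatase, read 20.3 ± 2.86 against 53.4 ± 1.82 CPM (-1.39 ± 0.29). Ly6h, a membrane protein of neurons, read 4.6 ± 1.85 against 20.1 ± 5.59 CPM (-2.12 ± 0.29), and Serpine2, a protease inhibitor, 27.6 ± 4.84 against 73.7 ± 13.3 CPM (-1.41 ± 0.22). Sema3e, a guidance cue, read 21.4 ± 3.98 against 54.7 ± 9.39 CPM (-1.35 ± 0.22). Fas, a death receptor, read 0.484 ± 0.38 against 6.12 ± 3.82 CPM, and Il1rn, an interleukin receptor antagonist, 1.94 ± 0.885 against 12.4 ± 10.1 CPM. Ccl2, a chemokine for monocytes, read 5.34 ± 2.07 against 74.5 ± 59.4 CPM, and Fosb, an immediate early factor, 3.22 ± 1.78 against 37.1 ± 22.4 CPM. Tagln, Tpm2 and the collagen Col1a1 read 0.755 ± 0.345 against 13.1 ± 17.5, 1.62 ± 0.279 against 13.4 ± 13.6 and 0.647 ± 0.806 against 12.7 ± 14.5 CPM. Of the 24 probes named for this comparison 9 passed in all 7 fits with 1 library left out, among them Irx1, Ly6h, Serpine2, Sema3e and Fas. The number passing was 13, 12 and 23 without female replicates 1, 2 and 3 and 19, 14, 16 and 23 without male replicates 1, 2, 3 and 4, and all 24 kept their direction.

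Camera called 18 lists between the sexes, and the smallest adjusted p with an estimated correlation was 0.11. Alpha cell genes had a median of -0.87 in males, with 4 probes passing as lower over all probes, and 1 as higher and 7 as lower adjusted over the list alone (camera adjusted p = 3.3e-08, adjusted p = 0.11 with an estimated correlation). Beta cell identity had a median of 0.32, with 4 probes passing as higher over all probes and 7 adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.27 with an estimated correlation). Stellate and fibroblast genes had a median of -2.77, with 3 probes passing as lower over all probes and 15 adjusted over the list alone (camera adjusted p = 6.3e-10, adjusted p = 0.12 with an estimated correlation), and the median was -0.40 without female replicates 1 and 2. Inflammatory and NF-kB genes had a median of -0.86 with 34 of 35 probes lower (camera adjusted p = 2.4e-07, adjusted p = 0.27 with an estimated correlation). Disallowed genes had a median of -1.12, with 2 probes passing as lower over all probes and 8 adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.11 with an estimated correlation). Of these 2, Acot7, a thioesterase, read 1.77 ± 0.43 against 10.2 ± 6.18 CPM and Hk1, a hexokinase with high glucose affinity, 4.56 ± 1.67 against 12.9 ± 8.15 CPM. The fold change of Hk1 turned sign without the 3 libraries that lay apart, which leaves 1 female. Also called were unfolded protein response (0.27), integrated stress response (0.40), secretion machinery (0.04), cholesterol synthesis (0.17) and oxidative phosphorylation (0.16) as higher in males. Aryl hydrocarbon receptor targets (-1.41), interferon response (-0.51), immediate early genes (-0.27), delta cell (-0.85), PP cell (-0.87), endothelial cell (-0.24), macrophage and dendritic cell (-0.58) and lymphocyte (-2.57) were called lower. Without female replicates 1 and 2, which leaves 1 female, 2 of the 18 medians turned sign (secretion machinery -0.12, endothelial cell 0.03) and 8 shrank by over 1.5 times, among them receptor targets (-0.59), beta cell identity (0.03), disallowed genes (-0.45) and lymphocyte (-0.81). Alpha cell (-1.07) and inflammatory and NF-kB genes (-0.62) were among the 8 that did not.

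Interactions asked whether an effect differed between groups, and none passed for a gene. For TCDD by diet in females Gm648 had the smallest p, with a log2 interaction of 2.18 ± 0.44 (edgeR adjusted p = 0.55). It was followed by Mal, Adgrv1, an adhesion receptor (3.37 ± 0.78), Tns3 (1.19 ± 0.29) and Haus8, of the spindle (2.55 ± 0.61), with an edgeR adjusted p of 0.59 each. In edgeR 0 probes passed, 1245 had an unadjusted p under 0.05, DESeq2 called 10, and edgeR called 1 without replicate 3 of oil-treated females on chow. For TCDD by sex on HFD Kdr had 1.65 ± 0.38 (edgeR adjusted p = 0.94), B4gat1, a glycosyltransferase, 2.33 ± 0.58, and Zfp39 1.10 ± 0.28. S100g, a calcium-binding protein, and Gm5239 had smaller p values but read 0 in 6 and 4 of the 7 libraries of 1 arm. In edgeR 0 probes passed, 833 had an unadjusted p under 0.05 and DESeq2 called 5. For HFD by sex with oil Krt23 had 5.91 ± 1.10 (edgeR adjusted p = 0.22), Ins2 -1.13 ± 0.23 (0.32), Cry1 -1.34 ± 0.31 (0.32), Meis3, a homeobox factor, -1.65 ± 0.36 and Acot7 3.12 ± 0.71. In edgeR 0 probes passed, 2158 had an unadjusted p under 0.05, DESeq2 called 39, and edgeR called 20 without replicate 3 of oil-treated females on chow, including Krt23, Ins2 and Acot7 (adjusted p = 0.025, 0.025 and 0.047), and 1, Krt23, without replicate 4 of oil-treated males on chow (0.038). Camera called 9, 7 and 12 lists for the 3 interactions, and the smallest adjusted p with an estimated correlation was 0.073, for apoptosis and p53 targets in TCDD by diet.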

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

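The acinar covariate and the exclusion of libraries that stand apart, both for diet in TCDD-treated females, the test for other cells in libraries of oil-treated females on chow, the list medians without 2 of those libraries, the diet change without libraries with Y-linked counts, and the splits of autosomal probes were chosen only after the result was seen.

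In 100 checks of groups of 4 mice, 5 values lay far from the others of their group, and chance gives about 5. The acinar share was 15.7% in replicate 1 of TCDD-treated females on chow and 2.88 to 4.18% in the other 3. The glucagon share was 6.34% in replicate 2 of the same group and 3.49 to 3.87% in the others. In replicate 1 of TCDD-treated males on HFD insulin took 8.65% against 9.36 to 9.45%, and the weak Ins1_30990 read 8.81 CPM against 4.18 to 4.57 CPM. In replicate 3 of that group Cyp1b1_72511 read 0.939 CPM and 0 in the others.

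Camera with the preset correlation called 28 lists in the tests of whether an effect differed between groups, and none passed with an estimated correlation. For TCDD by diet in females the median log2 interactions were 1.74 for receptor targets, -0.55 for beta cell identity, -0.34 for secretion machinery, 0.80 for disallowed genes, -0.26 for oxidative phosphorylation, -0.58 for interferon response, -0.62 for immediate early genes, 0.46 for apoptosis and p53 targets and 2.43 for stellate and fibroblast genes. For TCDD by sex on HFD (male minus female effect) they were 0.47 for beta cell identity, 0.22 for secretion machinery, 0.39 for inflammatory and NF-kB genes, 0.62 for interferon response, -0.24 for apoptosis and p53 targets, -0.43 for acinar cell and -1.20 for stellate and fibroblast genes. For HFD by sex with oil (male minus female effect) they were -0.57 for unfolded protein response, -0.32 for integrated stress response, -0.23 for beta cell identity, -0.13 for secretion machinery, 1.09 for disallowed genes, -0.63 for prolactin and serotonin genes, -0.16 for circadian clock, -0.37 for cholesterol synthesis, -0.35 for glycolysis, -0.45 for immediate early genes, 0.76 for macrophage and dendritic cell and 3.44 for stellate and fibroblast genes. The first and the last of these tests share the oil-treated females on chow. Without replicates 1 and 2 of that group 1 of 9 and 2 of 12 medians did not keep their sign and 6 in each shrank by over 1.5 times, with receptor targets at 0.24 and disallowed genes at -0.56 for TCDD by diet.

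Y-linked genes, which females do not carry, read 5.63, 2.77 and 4.18 CPM in replicates 1 and 3 of TCDD-treated females on chow and replicate 3 of TCDD-treated females on HFD, against at most 0.222 CPM in oil-treated females, and the source of these counts was not tested. The single TCDD-treated male on chow, which entered none of the 11 comparisons, lay above all 4 oil-treated males on chow for 4 of 20 panel probes and below them for 5. For 1 library set against 4 such positions are frequent by chance alone. Cyp1a1_29719 read 32.8 CPM against 5.23 to 32.7 CPM, Tiparp_65035 107 against 44 to 66.6 CPM, Tiparp_30478 0.67 against 0 to 0.332 CPM, and Ins1_72175 32500 against 23300 to 30500 CPM. Below them were Slc2a2_29578 at 7.37 CPM, Ins1_30990 at 2.39 CPM, Iapp at 11400 CPM, Ucn3 at 22.7 CPM and G6pc2 at 49.9 CPM.

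Between HFD and chow 887 probes differed in TCDD-treated females by a median log2 of 0.86, and the same probes by 0.44 in oil-treated females. The acinar share is argued against as the whole cause. With the acinar score as a covariate the median was 0.80, and all 887 probes kept their sign. Without the 3 libraries that stand apart the median was 0.81, again with all 887 probes of the same sign. Of these 3 libraries only replicate 2 of TCDD-treated females on chow is in this comparison. The exclusion could hardly lower the median, so it cannot decide whether they are the cause. Calls fell to 277 and 200 in these fits, which hold a further term or fewer libraries, while the change itself stayed at 93.3% and 94.2%. Without the 3 libraries with Y-linked counts, which leaves 2 chow and 3 HFD libraries, calls fell to 1, the median was 0.79 (92.1%) and all 887 probes kept their sign. The libraries left had also served to choose the 887 probes, so their median and signs could hardly change. This fit therefore cannot decide whether the change is robust to the libraries with Y-linked counts. Group size and the selection of strong probes cannot be told apart from a larger response, because the 500 probes chosen in 2 against 2 TCDD libraries changed more in the libraries left out than in oil-treated females in 32 of 36 halvings, with medians of 0.79 and 0.56, and probes chosen in oil-treated females changed more there in 5 of 9. A stronger diet response after TCDD may be named as a hypothesis only, as the interaction passed for 0 genes in edgeR (1245 at unadjusted p under 0.05, DESeq2 10).

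Stellate and fibroblast genes read 213 and 502 CPM in replicates 1 and 2 of oil-treated females on chow, and in the 3 comparisons that share this group the list's median log2 was -1.89 for TCDD, -3.49 for diet and -2.77 for sex. A raised background of weak probes is argued against as the whole source, since other probes of the same level lay above replicate 3 by 0.61 and 0.25 log2 against 1.70 and 1.91 for the list, at most 35.9% of it. For part of the rise in replicate 1 it stays open, as 27383 probes had counts there against 23217 in replicate 3. Without the 2 libraries the list's median was 0.23 for TCDD, -1.04 for diet and -0.40 for sex, and replicate 3 read 75.6 CPM, within the 50.9 to 161 CPM of the other 23 libraries. Collagen-making cells carried over into these 2 libraries may be the source, and this stays a hypothesis. A difference in these 2 mice themselves was not tested.

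Splits of the same libraries into groups of the same sizes were counted, with the real one among them. For HFD against chow in TCDD-treated females 1 of 35 splits gave as many passing probes, the real one with 887, and the highest other gave 2. This share of 0.029 is the smallest that 35 splits can give. It lies under 0.05 for this comparison taken alone, which argues against chance without excluding it. For males against females it was 1 of 35, with 274 against 16 at most, which decides nothing, since 32 of the 274 were Y-linked and only the real split can give them. With the 21571 autosomal probes alone it was 1 of 35, with 135 against 16 at most. This too is the smallest share that 35 splits can give. For this comparison taken alone it argues against chance for autosomal probes without excluding it. For HFD against chow in oil-treated females 1 of 10 splits gave 22 and the highest other 0, and 10 splits are too few for a share under 0.05. Where the real split passed 0 probes, probes with an unadjusted p under 0.05 were counted, and chance could not be excluded. For TCDD it was 19 of 35 in females on chow (real 795, highest other 3599), 2 of 35 in females on HFD (1439 and 1470), 31 of 35 in males on HFD (435 and 4401) and 21 of 100 for the mean (1125 and 3676). For HFD in oil-treated males it was 24 of 35 (764 and 2686). For the interactions it was 11 of 100 for TCDD by diet (1245 and 2607), 38 of 100 for TCDD by sex (833 and 4216) and 10 of 100 for HFD by sex (2158 and 5372). Splits with several times the real count point to a structure of the samples that the groups do not carry. At an adjusted p under 0.05 the highest such splits passed 1433 and 987 probes in males on HFD and 463 in females on chow. After Benjamini-Hochberg adjustment over the 11 comparisons the lowest share was 0.16, which is not under 0.05. A state of the mice other than diet that lay along the diet groups stays open too, as the 887 probes also varied together among male libraries (r = -0.99).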

How the results depend on the processing

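Chosen only after the result was seen were the acinar score as a covariate, the exclusion of 3 libraries that stand apart, the exclusion of 3 female libraries with Y-linked counts, the table without acinar probes, leaving 1 library out of both arms, and list medians without 2 oil-treated females on chow.

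The number of passing probes moved by over 1.5 times as follows, and the causes of these moves were not tested. DESeq2, which has its own spread and outlier rules, called 13, 41, 3 and 2 probes for TCDD in females on chow, females on HFD, males on HFD and the mean, 556 for HFD in oil-treated females, 2173 in TCDD-treated females, 785 for sex, and 10, 5 and 39 for the interactions of TCDD by diet, TCDD by sex and HFD by sex. Without a filter HFD in oil-treated females gave 40 and TCDD in females on chow 1, and without robust estimation the latter gave 5. The stricter filter gave 1639 for HFD in TCDD-treated females. The plate part as a factor gave 670 for HFD in oil-treated females, 599 for sex and 1 for HFD by sex. Probes summed per symbol gave 0 for HFD in oil-treated females. A fit of only the groups compared, which estimates the spread from fewer libraries, gave 153 for TCDD in females on HFD, 1209 for HFD in oil-treated females, 1357 in TCDD-treated females, 164 for sex and 4 for TCDD by diet. The acinar covariate gave 277 for HFD in TCDD-treated females, 264 of them among the 887, and 1 for TCDD in females on HFD. Without the 3 libraries that stand apart, so with fewer samples, the counts were 200 for HFD in TCDD-treated females (186 among the 887), 0 in oil-treated females, 11 for sex and 2 for TCDD in females on HFD. Without the 3 female libraries with Y-linked counts, again with fewer samples, they were 1, 0 and 168 for the first 3 of these.

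With 1 library left out the counts ran from 132 to 1769 for HFD in TCDD-treated females, 0 to 458 in oil-treated females, 73 to 704 for sex, 0 to 21 for TCDD in females on chow, 0 to 20 for HFD by sex and 0 to 1 for TCDD by diet, and were 0 in each fit of the other 5. With 1 library left out of both arms HFD in TCDD-treated females gave 11 to 1635. RLE and upper-quartile scaling gave 1060 and 1093 for HFD in TCDD-treated females and 22 and 20 in oil-treated females, and moved the median log2 fold change by at most 0.064. No paired analysis was possible because each animal number occurs once.

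Among named probes 2980 values under an alternative kept direction and side of the threshold, 983 lost the call, 57 gained one and 9 reversed. Reversed without the 3 libraries that stand apart, where 1 oil-treated female on chow is left, were Cyp1a1_29719 (-0.12), Cyp1a1_79654 (-0.18) and Mal (1.91) for TCDD in females on chow, Mal for TCDD by diet (-0.40), and Hk1 for sex (0.06). For TCDD in males on HFD Tiparp ran from -0.15 to 0.46 and Nqo1 from -0.01 to 0.77 with 1 library left out. Camera gave 105 of 363 list calls with the preset correlation and 0 with the estimated one. Fry, which tests another hypothesis, gave 15, or 68 with members free to go either way. Depth limits probes near 0.744 CPM, and of 100 probes changed 2-fold at this group size 26 were called in HFD against chow of TCDD-treated females.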

Other observations

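Both tests in this part were fixed before their result was seen, on probes chosen in TCDD-treated females.

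Probes that were higher and probes that were lower on HFD than on chow in TCDD-treated females also varied against each other among the 12 male libraries, which are in neither arm of that comparison. The mean score of the higher probes and that of the lower probes had a Pearson r of -0.99 (permutation p = 1e-05, the smallest that 100000 permutations can give, Benjamini-Hochberg adjusted 2e-05 over 2 relations) and a Spearman rho of -0.94 (permutation p = 3e-05, adjusted 6e-05). Without the 2 libraries farthest from the median r was -0.98, and within the male groups of at least 3 mice it was -0.99 over 11 libraries. Of 1000 random probe sets matched on mean level 0 gave a correlation as low, with a median of 0.67 and a middle 95% of 0.13 to 0.90, which fits a shared state of the libraries. The acinar share is argued against as the whole cause, since the correlation was -0.99 after the acinar score was removed, with random sets at 0.29 to 0.91.

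The score of higher minus lower probes was 1.25 ± 0.29 in TCDD-treated females on HFD (n = 4), 0.27 ± 0.10 in oil-treated females on HFD (n = 3), -0.66 ± 0.01 in oil-treated females on chow (n = 3) and -0.66 ± 0.45 in TCDD-treated females on chow (n = 4). The probes were chosen for differing between the TCDD-treated females on HFD and on chow, so the gap between those groups follows from that choice. The same choice may raise 1.25 above 0.27. In males it was -0.32 ± 0.45 with oil and chow (n = 4), -0.23 ± 0.61 with oil and HFD (n = 3), -0.03 ± 0.61 with TCDD and HFD (n = 4) and 0.88 in the single TCDD-treated male on chow. Against the acinar score the correlation among male libraries was 0.56 (permutation p = 0.064, adjusted 0.064), rho 0.55 (permutation p = 0.068, adjusted 0.068), 0.32 without the 2 farthest libraries, and 0.60 within groups. The nature of this state was not tested.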
